A study of Aspergillus niger with 4 samples.

How the data were processed

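RNA was measured by sequencing in mycelium of the filamentous fungus Aspergillus niger. There were 4 libraries, 2 from a reference strain and 2 from a strain in which the gene hapX had been replaced by a hygromycin resistance marker. Per the labels' protocols, mycelium was grown for 16 h in rich medium with 2% fructose, washed, moved to 50 ml of minimal medium at pH 6 with 25 mM maltose, and frozen 2 h later. Messenger RNA was purified and sequenced as single-end reads on an Illumina HiSeq instrument by a service provider, per the labels' protocols. Nothing in the labels says whether the 2 libraries of a strain came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Where a p-value comes from shuffling or counting genes, it does not measure that spread.

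Per the series' design text, the NRRL3 strain of A. niger served as the reference for read mapping. The submitters' processing notes name Bowtie2 and HISAT. Which tool quantified the genes, the annotation release, the strandedness of the library and any filter are not given in the sources used here. The deposited table of each library gives, per the file headers, a gene length, an expected count (an estimated number of reads per gene, not normalized) and an FPKM value (scaled to gene length and to the number of mapped fragments, computed by the authors). Each table lists only genes with a count above 0, from 10175 to 10280 genes, and 10898 genes are listed in at least 1 table. A gene missing from a table was set to 0. Every listed length is a multiple of 3, so it is a coding length and the gene models hold no untranslated regions. Between 24 and 37 listed genes per library, at most 0.362%, had an expected count that was not whole (any decimal other than 0, with counts given to 2 decimals), and expected counts were rounded to whole numbers.

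Expected counts summed to 4264311 and 4142850 in reference libraries a and b and to 3840181 and 3505555 in delta-hapX libraries a and b. A count of 3, used as the floor for a gene at 0, corresponds to 0.704, 0.724, 0.781 and 0.856 CPM (counts scaled to a common library size) in that order. Reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

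The gene identifiers carry the NRRL3 prefix. The only table of gene names at hand covers another assembly, ASM285v2, and 0 of the 10898 identifiers matched it. The lists of pathways fixed before the data were examined (starch and maltose degradation, siderophores and iron uptake, heme and iron-sulfur synthesis, respiration and others) could therefore not be filled, and the planned tests of those lists were not run. The level of hapX itself is not reported for the same reason. The tables give no coordinates, and no genome sequence was used here.

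The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the rounded counts of all 4 libraries, with group as the only term, TMM normalization, edgeR's default filter on low counts (filterByExpr) and Benjamini-Hochberg adjustment at 0.05. A total of 8535 genes were tested, holding 99.8% of all counts. Fold changes are log2 values of delta-hapX over reference, and standard errors were derived from the fold change and its F statistic. Fitted fold changes of genes with almost no counts in a group depend on edgeR's prior count. For those, the ratio of summed counts per effective library size is given with its exact (Clopper-Pearson) 95% interval.

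Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter or a filter of 10 counts in every library of a group, the replicate letter as a block, DESeq2's Wald test (version 1.42.0), limma (version 3.58.1) with a trended variance on log2(FPKM + 1) over genes with an FPKM of 1 or more in at least 2 libraries, the same with a pseudocount of 0.1 or with no filter, and leaving out each library in turn. Library totals without TMM and a fit with the trend of fold change on coding length removed by an offset were added after the data had been seen. The labels give both groups the letters a and b without saying that a letter pairs libraries. The deviations of same-lettered libraries from their group means had a correlation of 0.0196 across genes, and the libraries were not treated as paired.

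The rule for named genes was fixed before the data were examined: with no gene names, the 2 genes with the largest change in each direction among those with adjusted p under 0.05, no overlap between groups and a mean of at least 5 CPM in the higher group. The grouping of genes by abundance, coding length and identifier number, and the set of abundant lower genes, were chosen after the data had been seen. Their quartiles were cut on the mean over all 4 libraries or on coding length among the tested genes.

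The fits were tested on simulated data for the 8535 tested genes, in 5 draws with 200 changed genes each. Each gene had its own mean and a dispersion taken from the trend of dispersion with abundance. The spread of dispersions around that trend was not simulated, and fewer genes changed than were called in the data. Recovery and false calls in the real data may therefore differ. For delta-hapX against reference at these depths, edgeR recovered 35.8% of genes changed 1.5-fold, 69.3% of those changed 2-fold and 92.1% of those changed 4-fold, and 3.10% of its calls were false. DESeq2 recovered 22.1%, 53.7% and 83.6% in that order, with 0.376% false calls. Limma on log2(FPKM + 1) recovered 21.8%, 61.2% and 90.3%, with 5.73% false calls.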

Results

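Gene expression was profiled in A. niger mycelium 2 h after transfer to 25 mM maltose, the disaccharide released from starch. The reference strain, N593 delta-kusA, lacks kusA, a deletion used to favour targeted gene replacement, and the mutant carries the hapX deletion in addition. HapX is a transcription factor of filamentous fungi that acts with the CCAAT-binding complex and is known for its part in iron homeostasis. The design asks which transcripts depend on hapX during growth on maltose. There were 2 libraries per strain, with 3505555 to 4264311 expected counts each. Log2 CPM values had a Pearson correlation across genes of 0.988 between the reference libraries, 0.986 between the delta-hapX libraries and 0.967 to 0.969 between libraries of different strains. The replicates of each strain differed by more than sampling noise, with a chi-square per gene of 6.56 in the reference and 3.79 in delta-hapX, which argues against 1 library deposited more than once but not against repeated preparations of 1 RNA sample, and each library was counted as 1 replicate. Between strains this value was 39.6 to 41.6.

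Deletion of hapX was accompanied by changes in 2269 of the 8535 genes tested, or 26.6%. Of these, 1044 were higher and 1225 were lower in delta-hapX (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 2 per strain). In all 2269 genes both delta-hapX libraries lay on the same side of both reference libraries. Selection by the test favours such genes, so this is no added evidence for the calls. Of all tested genes, 63.4% were separated in this way, where chance gives 33.3%. At least a 2-fold change was reached by 368 higher and 400 lower genes, and at least a 4-fold change by 79 higher and 78 lower genes (53 and 67 by limma on log2(FPKM + 1) with the filter). The median size of the change was 0.76 on the log2 scale for higher genes and 0.78 for lower genes. Across all tested genes the strain means differed by a median of 0.32 on the log2 scale, whereas the replicates differed by 0.19 in each strain. DESeq2's Wald test called 1380 genes, 570 higher and 810 lower, of which 1377 were also called by edgeR with the same direction. Limma on log2(FPKM + 1) called 1681 with the filter and 1201 with no filter.

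**Figure D1:**
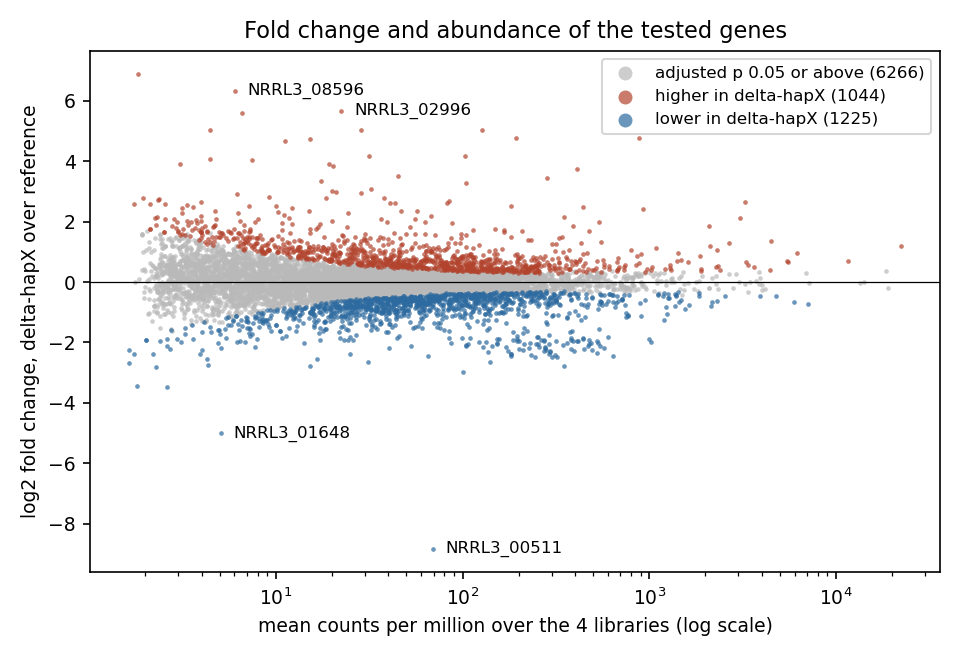
Log2 fold change of delta-hapX over reference (vertical axis) against the mean CPM over the 4 libraries (horizontal axis, log scale), with 1 point for each of the 8535 tested genes. Red points are the 1044 genes higher and blue points the 1225 genes lower in delta-hapX at an adjusted p under 0.05, and the 4 named genes are marked.

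NRRL3_00511, a gene model with a coding length of 1488 bases, had the largest fall among the tested genes that met the rule for named genes. It was represented by 685 and 492 reads in the reference libraries and by 1 read in each delta-hapX library. Its level was 139 ± 27.7 CPM in the reference and 0.275 ± 0.0212 CPM in delta-hapX (mean ± SD, n = 2 each). By summed counts it was 508 times as abundant in the reference, with a 95% counting interval from 140.2 to 4197, and edgeR's adjusted p was 2.44e-12. NRRL3_01648, with a coding length of 678 bases, also dropped to 1 read in each delta-hapX library, from 40 and 43 reads in the reference. This corresponded to 9.84 ± 0.831 CPM against 0.275 ± 0.0212 CPM (mean ± SD, n = 2 each) and a ratio of 35.8 (95% counting interval 9.60 to 300.5; edgeR adjusted p = 1.26e-05). The files pair neither identifier with a name or function.

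In the opposite direction, NRRL3_08596 (777 bases) and NRRL3_02996 (1305 bases) rose from close to the detection floor. NRRL3_08596 had 1 and 0 reads in the reference libraries and 41 and 46 in the delta-hapX libraries. Its mean went from 0.116 ± 0.164 to 12.01 ± 1.89 CPM (SD, n = 2 each), a ratio of 100.8 with a 95% counting interval from 17.6 to 4028 (edgeR adjusted p = 2.66e-06). Its fitted log2 fold change of 6.32 became 8.51 without reference library a and 5.51 without reference library b. NRRL3_02996 had 2 and 5 reads in the reference libraries and 156 and 164 in the delta-hapX libraries. It went from 0.837 ± 0.530 to 44.1 ± 4.95 CPM (SD, n = 2 each), a ratio of 52.99 with a 95% counting interval from 25.4 to 132.9. Its fitted log2 fold change of 5.68 (SE 0.36; edgeR adjusted p = 8.69e-10) became 5.14 without reference library a and 6.47 without reference library b. All 4 genes kept their direction and an adjusted p under 0.05 in the 14 alternative fits, but the size of the change moved. Limma on log2(FPKM + 1) gave log2 fold changes of 3.85 for NRRL3_08596, 4.41 for NRRL3_02996, -6.30 for NRRL3_00511 and -3.49 for NRRL3_01648. In that order edgeR fitted 6.32, 5.68, -8.83 and -5.01. Limma on log2(FPKM + 0.1) gave 6.27, 5.61, -8.36 and -4.88, so the sizes by limma depended on the pseudocount.

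**Figure D2:**
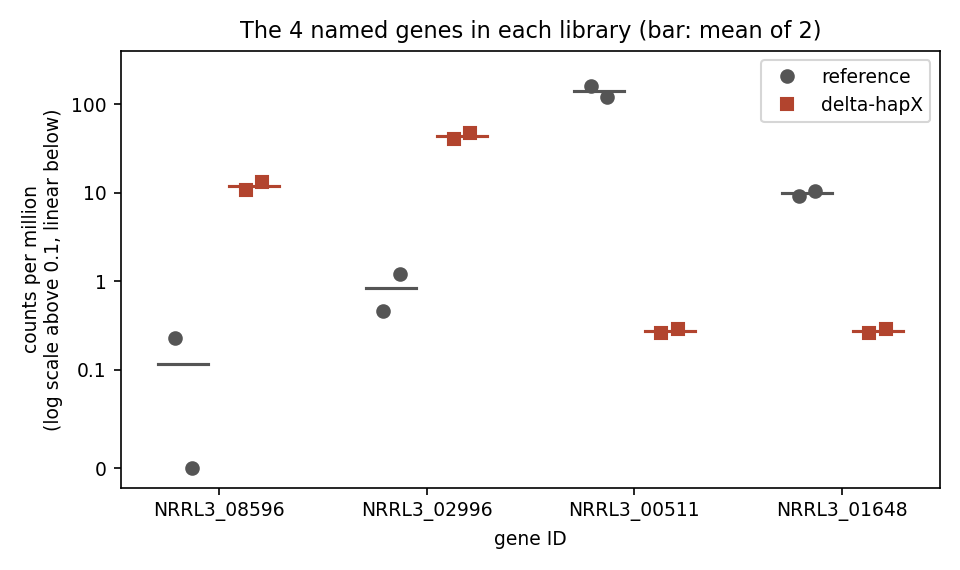
CPM of the 4 named genes in each library (vertical axis, log scale above 0.1 and linear below), with circles for the reference, squares for delta-hapX and a bar for the mean of 2 libraries. NRRL3_00511 and NRRL3_01648 sit at 0.275 CPM in delta-hapX, and NRRL3_08596 and NRRL3_02996 rise to 12.01 and 44.1 CPM.

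A set of abundant genes fell together by about 4-fold. Among the 2134 genes of the most abundant quartile (93.3 CPM or more), 90 were lower in delta-hapX at an adjusted p under 0.05 with a log2 fold change of -1.5 or below, against 24 that were higher by the same limit. Their median log2 fold change was -2.03, with an interquartile range from -2.23 to -1.90, and their median level was 267 CPM. The fold changes of the abundant genes had a second peak there. A total of 63 genes lay between -2.3 and -1.8, against 17 between -1.8 and -1.3, the interval nearer to 0 (exact two-sided binomial test, p = 2.3e-07). The intervals were chosen after the values were seen, and the test counts genes as independent, which they are not. On the side of higher genes the numbers went the other way, with 16 genes from 1.3 to 1.8 and 5 from 1.8 to 2.3. The 90 genes held 4.68% and 4.15% of the counts of the reference libraries and 1.06% of each delta-hapX library. They were short: their median coding length was 508.5 bases, against 1599 for the whole quartile (permutation test, p = 0.0001, the smallest that 10000 draws can give), and 72 of the 90 belonged to the shortest quartile of tested genes. Leaving out any one library, the median log2 fold change of these 90 genes, which were chosen by their change in the same libraries, ranged from -2.13 to -1.94.

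**Figure D3:**
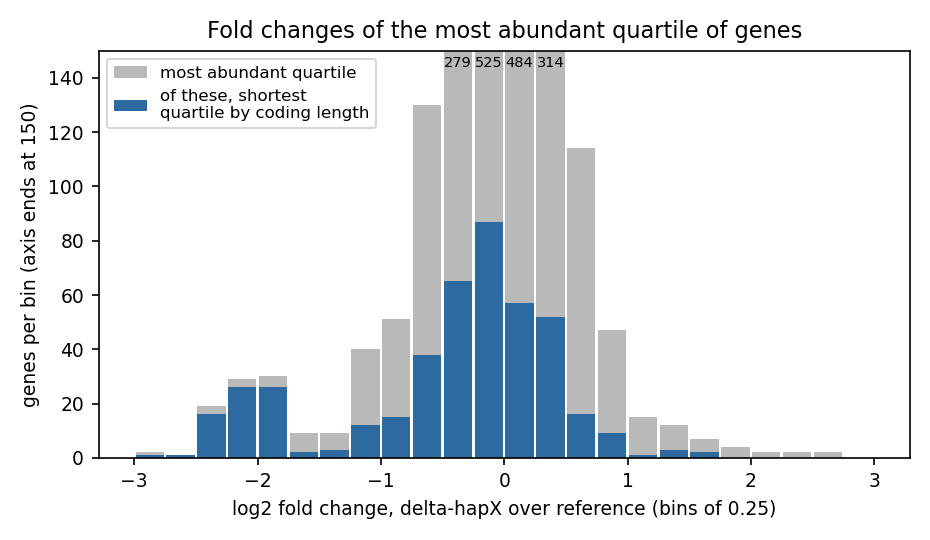
Number of genes (vertical axis, ending at 150, with the numbers of taller bins written in) per bin of 0.25 in log2 fold change of delta-hapX over reference (horizontal axis), for the 2134 genes of the most abundant quartile. Grey bars are all of these genes and blue bars those that also belong to the shortest quartile by coding length, and a separate peak near -2 consists mostly of short genes.

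The direction of change varied with coding length more widely. In the shortest quartile of genes (75 to 903 bases), 184 genes rose and 427 fell, so 69.9% of the called genes were lower. DESeq2 called 101 higher and 288 lower genes there, and edgeR without delta-hapX library b called 117 and 322. The next quartile (906 to 1356 bases) had 242 higher and 300 lower genes, the third had 314 and 278, and the longest (1938 bases or more) had 304 and 220. Fold change and coding length had a Spearman correlation of 0.13 (Pearson r = 0.12) across genes, which are not independent replicates (permutation p = 0.0001, the smallest that 10000 shuffles can give). All 4 differences between a single delta-hapX and a single reference library gave a rho of 0.12 to 0.13. The corresponding rho was 0.0030 between the reference replicates (permutation p = 0.78) and -0.00022 between the delta-hapX replicates (permutation p = 0.98).

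Among the least abundant quartile of genes (1.64 to 11.6 CPM), higher calls outnumbered lower ones, at 172 against 105. The median log2 fold change of all 2134 genes of that quartile, 1857 of them not called, was 0.139. It was -0.0238, -0.0373 and -0.0229 in the other quartiles, from low to high abundance. In each of the other quartiles lower calls were more numerous, and the most abundant quartile had 378 higher and 476 lower genes. At the very top, among the 100 most abundant genes (1198 CPM or more), 30 rose, 25 fell and 45 did not pass the test. The 100 most abundant genes of the 2 strains had 82 members in common. Of the 18 genes that ranked there only in delta-hapX, 14 passed the test, the largest change being 27.5-fold. The lowest reference mean among these 18 genes was 61.4 CPM. Of the 18 that ranked there only in the reference, 16 passed the test. Ranking in 1 strain only fixes the direction of these changes. The 100 most abundant genes held 31.4% ± 0.881 of the counts in the reference and 35.6% ± 0.125 in delta-hapX (mean ± SD, n = 2 each; exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries allow).

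**Figure D4:**
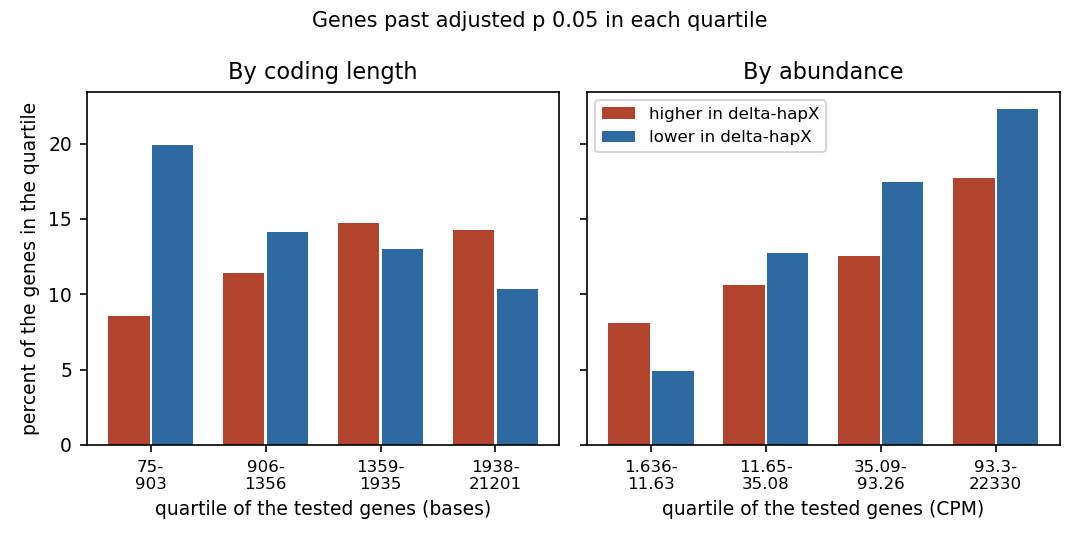
Percent of genes (vertical axes, from 0) called higher (red) or lower (blue) in delta-hapX at an adjusted p under 0.05, in quartiles of the 8535 tested genes by coding length in bases (left) and by mean CPM (right). In the shortest quartile 8.57% of genes were higher and 19.9% lower, and in the least abundant quartile 8.06% were higher and 4.92% lower.

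Genes with consecutive identifier numbers tended to change alike. Among the 368 genes that rose at least 2-fold there were 5 runs of at least 3 consecutive numbers, holding 18 genes, with a longest run of 6. Shuffling the calls over the tested genes gave 0.464 such runs on average (permutation p = 0.0002). NRRL3_02996 belonged to one of them, a run of 3. The 400 genes that fell at least 2-fold formed 7 such runs, holding 25 genes, with a longest run of 5, against 0.594 on average when shuffled (permutation p = 0.0001, the smallest that 10000 shuffles can give). Over all tested genes, the log2 fold changes of genes 1 number apart had a Pearson correlation of 0.195 across 7062 pairs (permutation p = 0.0001, again the smallest possible). The correlation was 0.101 at a distance of 2, 0.049 at 3 and 0.018 at 5. For the difference between replicates, the correlation at a distance of 1 was 0.045 in the reference (permutation p = 0.0003) and 0.022 in delta-hapX (permutation p = 0.068).

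**Figure D5:**
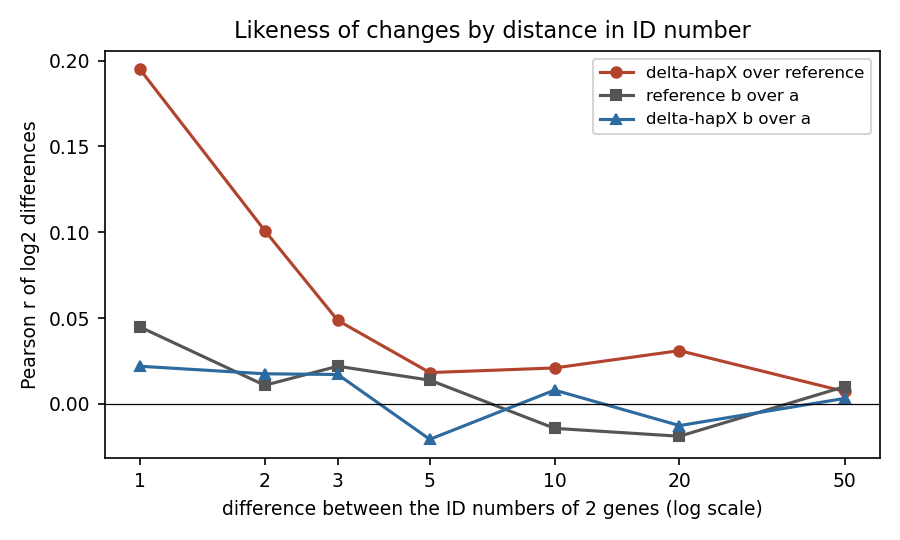
Pearson correlation (vertical axis) of log2 differences between genes whose identifier numbers lie 1 to 50 apart (horizontal axis, log scale), for delta-hapX over reference (circles) and for the replicates of the reference (squares) and of delta-hapX (triangles). The difference between strains falls from 0.195 at a distance of 1 to 0.018 at a distance of 5.

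Whether the identifier numbers follow the order of genes on the chromosomes is not stated in the sources used here. Each result rests on 2 libraries per strain, and the labels record no batch.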

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

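The number of changed genes depended on the tool and, with limma, on the filter; edgeR called 2462 with no filter and 2296 with at least 10 counts in every library of a group. The main count of 2269 became 1380 with DESeq2's Wald test (570 higher, 810 lower, and 229 of the higher genes at least 2-fold). It became 1201 with limma on log2(FPKM + 1) and no filter (487 higher, 714 lower, and 239 of the higher genes at least 2-fold). With limma on filtered FPKM values it was 1681 (680 higher) with a pseudocount of 1 and 1556 (635 higher) with 0.1. The cause of these differences was not tested on the real data, but in the simulations DESeq2 and limma also recovered fewer of the changed genes than edgeR. In total, 74 of the 84 recomputed counts differed from the main value by at most 1.5-fold, in either direction, and 10 were lower by more than that. Leaving out 1 library gave 1591 (without delta-hapX library b) to 1922 changed genes and 661 to 814 changed at least 2-fold, with the lone library assumed to vary like the other strain's. With the replicate letter as a block, 2628 genes were called, including all 2269 of the main fit, and 811 at least 2-fold; the letters were not taken to pair the libraries, and the block changed no call on a named gene. Of the main calls tested in each alternative, 0 changed sign. The named genes kept their direction and an adjusted p under 0.05 in all 56 refits, with adjusted p-values up to 0.0031. In the simulations edgeR recovered 17 of 88 2-fold changes in the least abundant quartile of genes and 64 of 64 in the most abundant one, so calls on low genes are limited at these depths. The alternatives planned for the tests of pathway lists were not run, since no identifier matched a gene name.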

Other observations

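Tests chosen only after the result was seen were those on the shortest genes without the set of 90 (with and without the trend on length) and against the other length quartiles, on the single-library differences, on replicate differences, on the distance of 20 identifiers and on genes near 0; those of a smooth shift with length on all calls, of loss of short RNA and of near-identical neighbours were written down before their outcome was known, though the patterns they address had been seen.

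The strongest changes were mostly rises. At least an 8-fold change was called in 25 higher and 4 lower genes, and at least a 16-fold change in 15 higher and 2 lower genes. Higher genes outnumbered lower ones at the 8-fold limit in all 14 alternative fits, with 23 against 2 by DESeq2; 1 called gene had no reads in a strain, so its fitted fold change is no bound. The numbers themselves moved with single libraries, to 44 against 6 without reference library a, 35 against 10 without reference library b, 26 against 19 without delta-hapX library a and 29 against 12 without delta-hapX library b. Thinned to 3505554 counts, the delta-hapX libraries held 10246 and 10175 genes with at least 1 count, slightly more than the 10131 and 10135 of the reference libraries. These numbers come from a single random draw and were not tested. The delta-hapX libraries differed from each other by more than delta-hapX library b differed from either reference library. A total of 333 genes had reads only in delta-hapX and 294 only in the reference, of which 11 and 6 had 10 or more reads.

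Short genes fell more often than long ones, and a set of 90 abundant, mostly short genes fell about 4-fold. A loss in the delta-hapX libraries that followed coding length would lower every gene of that length and abundance alike. Of the most abundant quartile, 254 genes had the set's interquartile range of coding length, 44 set members included. Their median log2 fold change was -0.23, which argues against a loss by coding length as the origin of the 4-fold fall. The gene models hold no untranslated regions, so RNA length is not known and loss of short RNA itself stays open. The set alone does not account for the excess of lower calls in the shortest quartile. Of these calls 69.9% were lower, against 48.1% in the other quartiles. Without the set the share was 65.9% against 47.6% (odds ratio 2.13, 95% interval 1.73 to 2.62). With the trend on length removed it was 59.3% against 53.2% (odds ratio 1.29, 1.06 to 1.57, Fisher's exact test, two-sided p = 0.011, genes counted as independent). Genes with consecutive identifiers changed alike and the 90 genes fell together, so this interval may be too narrow. Whether a smooth shift with length alone accounts for the excess therefore stays open. With the trend removed and the set left out the share was 53.5% against 52.65% (odds ratio 1.03, 0.842 to 1.27). The trend was fitted to these same fold changes and the set was chosen from lower calls, so both steps push the odds ratio towards 1. It therefore cannot tell whether a smooth shift acted on the genes outside the set, and that stays open. An effect of RNA or library preparation shared by both delta-hapX libraries stays open. The smallest rho with length among the 4 single-library differences was 0.1227, and preparation cannot be told apart from genotype here. A shared regulation of the 90 genes that depends on hapX is a hypothesis that needs their names.

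Genes with consecutive identifiers changed alike, with a correlation of 0.195 at a distance of 1. Reads shared by overlapping neighbours could tie the replicate differences as well. These correlated at 0.0448 in the reference (permutation p = 0.0003) and 0.022 in delta-hapX. Replicates differed less than the strains did, so they held less change to share. The replicate values alone therefore do not decide the question. Overlap would mainly tie genes 1 number apart, yet the fold changes correlated at 0.101 at a distance of 2 and 0.0486 at 3. When shuffled, the correlation at a distance of 1 had an SD of 0.012. If the numbers follow the chromosomes, this argues against shared reads as the whole of the correlation. Whether they account for a part of the correlation cannot be decided from these values. A large segment with another copy number, as the whole of it, would keep the correlation high over many genes, but at a distance of 20 it was 0.031, still beyond chance (permutation p = 0.013), so a small contribution of segments stays open too. Reads divided between near-identical neighbours stay open, since the correlation of 0.197 without the 46 tested genes whose expected count was not whole in some library leaves out only 57 of 7062 pairs, and the quantifying tool is not known. Joint regulation of neighbouring genes is a candidate explanation if the numbers follow the chromosomes, which was not tested.

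With at most 3 reads in each delta-hapX library and at least 50 in each reference library, 1 gene stood out among the 6159 with that reference level, NRRL3_00511. With a minimum of 20 reads there were 2, the other being NRRL3_01648, while 5 genes had the reverse pattern. Loss of nearly all reads is what the deleted locus would show, so NRRL3_00511 may be the deleted gene; a silenced gene would look the same, and no source used here pairs the identifier with hapX, so this stays open.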
